A study of Mus musculus with 8 samples.

How the data were processed

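Total RNA and ribosome-protected fragments (RPF, the short pieces of mRNA that ribosomes shield from nuclease) were sequenced from testes of C57BL/6 mice at postnatal day 24. The mice were wild type (WT) or null for Miwi, the PIWI-clade Argonaute protein encoded by Piwil1. Per the labels, clarified lysates went either to RNA extraction and sequencing or to ribosome profiling. The labels list 8 libraries, 2 for each combination of genotype and assay, and number the replicates within each group. Groups and replicate numbers were taken from the sample titles. The series calls the libraries biological samples but the labels name no animals or litters, so p-values measure the spread between these libraries, part of which may be technical.

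The deposited tables hold 99671 transcripts of 21949 genes, one table for each replicate number and a merged one. The fragment counts are whole numbers per transcript, per the file headers, and were deposited by the authors without normalization. The submitters' processing notes name cutadapt 2.5, Bowtie 1.2.2, STAR 2.5.0a and the genome build GRCm38, with no role for each. The counting program and whether it used strand are not given in the sources used here. The deposited FPKM values were computed by the authors from those counts, from the length column and the fragment total of each library. Of the transcripts with a length, 84.7% had a length that is a multiple of 3, so this is a coding length and the counts cover coding sequence. The authors' translational efficiency is a ratio, the RPF FPKM over the RNA FPKM, which held within 1e-8 in 100% of the deposited rows. The authors' fold change per gene is the ratio of that efficiency between null and WT, and the authors deposited its log2 value beside it. Genes carried an Up or Down mark in the authors' deposited table from a change of 1.2-fold, with no replicate test. The merged counts equalled the sum of both replicate tables in all 99671 rows, so the merged table was used only as that check and for the authors' own changes.

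A fragment was counted for each transcript of a gene that it overlapped: counts summed over transcripts were 2.23 to 2.39 times those of the largest transcript of each gene. The transcript with the highest mean count therefore stood for its gene, as the plan had foreseen for such tables. Symbols came with a lookup of gene IDs. Genes that share sequence with close copies, such as histones, Hspa1a and Hspa1b, alpha globins, Tuba3a and Tuba3b, H2al3 and the Klk1b kallikreins, are uncertain because the treatment of multiply mapping fragments is not given. Reads from overlapping genes on opposite strands could not be told apart either.

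Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 16051. Library sizes were scaled by TMM over all 8 libraries. A quasi-likelihood model with robust dispersion was fitted to the 4 groups, leaving 4 residual degrees of freedom. Contrasts gave the null against WT change in RNA, in RPF and in translational efficiency (TE), the last as the interaction of genotype and assay. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. Errors beside log2 changes are standard errors (SE) from that model, and CPM values are counts relative to the TMM-scaled library size. The model gives each gene a single dispersion for both assays. Footprint replicates spread more than RNA replicates, yet the median SE at a mean CPM of at least 10 was 0.131 in RPF and 0.135 in RNA. Errors of RPF changes may thus be too small, and those of TE changes rest on the same pooled value. Because TMM centres most genes near 0, every change is relative to the bulk of genes in the same libraries, and no absolute amount of RNA or of ribosomes is measured. TE from counts is likewise relative: it compares shares of footprints with shares of RNA.

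The 20 gene lists were fixed before the data were examined: piRNA pathway, late spermiogenesis, acrosome, CREM program of round spermatids, meiotic prophase, pachytene to meiotic division, spermatogonia, Sertoli, Leydig, peritubular myoid and smooth muscle, macrophage and immune, endothelial and blood, cytosolic ribosomal proteins, translation initiation and elongation factors, RNA-binding translational regulators of germ cells, mitochondrially encoded, integrated stress and unfolded protein response, p53 response and apoptosis, heat shock and chaperones, and testis-specific energy metabolism. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the 20 lists. Camera with an estimated correlation and fry, a rotation test of whether a list moves one way on balance, were run beside it. Some genes stand in more than 1 list, among them Gapdhs, Pgk2, Hspa1l, Hspa2, Dmrt1, Boll and Kif17.

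The rule for naming genes was also fixed beforehand. It takes Piwil1 first and then, per contrast and direction, the 10 largest log2 changes among called genes with a mean CPM of at least 10 and the same sign in both replicates, without predicted genes. It adds for each list the members with the largest changes at that abundance. The analysis steps were tested on simulated data drawn from the real means and library sizes. Simulated changes of 2-fold were recovered for 42 of 67 changed genes in RNA (62.7%, with 15832 genes in the fit). In RPF the count was 45 of 67 (67.2%, 15830 genes in the fit) and in TE 28 of 67 (41.8%, 15825 genes in the fit). The changed genes were drawn only from those above a floor of abundance. For 4-fold changes the shares were 95.5%, 97% and 87.9%, and for 1.5-fold 17.9%, 14.9% and 9%. False calls made up 4 of 121, 12 of 131 and 8 of 100 calls. That simulation gave both assays a like spread, which the real libraries did not have. It also left most genes unchanged, 15632 of 15832 in RNA, while 5988 of 16051 were called in the real RNA comparison. With few changed genes the adjusted threshold is stricter, so these shares do not carry over to the real calls. In a simulated null with a lowered list, camera with the preset correlation, camera with an estimated one and fry each found that list and called 0 of the others. Genes were drawn independently there, so this could not show how the tests treat correlated lists. Estimated correlations of the real lists reached 0.225, for mitochondrially encoded genes in RNA.

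Alternatives planned beforehand were library sizes without TMM, DESeq2 size factors, the DESeq2 1.42.0 Wald test, TMM within each assay or without the 50 most abundant genes per assay, weaker and stricter count filters, the longest transcript, fits of each assay's own 4 libraries, replicate blocks, glmTreat against 1.5-fold, and leaving out each library in turn. DESeq2 gave no adjusted p for 312 genes in RPF and 2490 in TE, which stayed out of its calls. Removal of a trend on coding length, a crossed pairing of footprint libraries and the transcript marked canonical were chosen after seeing the data. No reference genome was used, so GC content was not analysed here.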

Results

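Ribosome footprints and total RNA were measured in whole testes of WT and Miwi-null mice at postnatal day 24, an age at which the leading wave of germ cells has passed meiosis and formed round spermatids. Each genotype and assay had 2 libraries. Total gene counts were 15597058 and 13877971 in the WT RNA libraries and 12725429 and 11134136 in the null RNA libraries. The WT RPF libraries held 28048613 and 17730684, and the null RPF libraries 11660509 and 28329164. A single count thus stood for 0.0353 to 0.0898 CPM. Across genes, replicates correlated at r = 0.991 within each RNA group, 0.987 in WT RPF and 0.988 in null RPF, and genes are not independent replicates. Replicate counts differed by more than sampling noise in all 4 groups, though to unlike degrees. The chi-square per gene was 4.14 in WT RNA, 1.19 in null RNA (p = 4e-46), 47.8 in WT RPF and 24.5 in null RPF. The null RNA pair thus lay close to counting noise but above it. The labels do not say whether these 2 libraries come from separate animals, so it is unknown whether null RNA SDs hold any spread between animals. They were kept as 2 samples.

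Piwil1 was nearly lost from the null libraries in both assays. This gene (ENSMUSG00000029423.10, chromosome 5, 128736071 to 128755474, GRCm38) encodes MIWI, which binds piRNAs in meiotic and postmeiotic germ cells. It had 8215 and 7165 counts in the WT RNA libraries against 46 and 26 in the null ones. Among footprints it had 14206 and 6868 counts in WT against 37 and 94 in null. The mean CPM was 542 ± 13 (SD, n = 2) in WT RNA, 2.89 ± 0.887 in null RNA, 436 ± 65.5 in WT RPF and 3.28 ± 0.0326 in null RPF. Its RNA fell by 7.53 ± 0.20 (SE) on the log2 scale and its footprints by 7.05 ± 0.19, with edgeR adjusted p-values of 7.34e-07 and 1.38e-07. Every library therefore carried the Piwil1 level that its genotype label calls for.

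The RNA comparison asked which transcripts differ in abundance when MIWI is absent. Piwil1 aside, the largest decreases included genes that package sperm DNA. Tnp2 and Tnp1, the transition proteins that replace histones in elongating spermatids, fell by 4.72 ± 0.12 and 4.20 ± 0.13 on the log2 scale. Prm2 and Prm1, the protamines that follow them, fell by 4.71 ± 0.19 and 3.88 ± 0.11. Of 20 peritubular myoid and smooth muscle genes 14 fell, Actg2 by 3.06 ± 0.13. Of 21 markers of steroid-producing Leydig cells 7 rose and 3 fell (list adjusted p = 0.309 with an estimated correlation), and Sult1e1, the estrogen sulfotransferase, rose by 3.99 ± 0.16. Of 16051 genes, 5988 were called in RNA, 2639 higher and 3349 lower in the null testes, and 950 and 1244 of these changed more than 2-fold.

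Of the 33 tested late spermiogenesis genes, 30 fell in RNA and 0 rose, with a median log2 change of -1.78 (camera adjusted p = 9.56e-50). The count was also 30 when adjusted over the list alone. Camera with an estimated correlation gave a list adjusted p of 0.0013. In mean CPM, Tnp2 went from 3342 ± 104 (SD, n = 2) in WT to 126 ± 3.31 in null and Prm1 from 2501 ± 94.2 to 170 ± 1.02. Prm1, Prm2, Prm3 and Tnp2 lie together on chromosome 16 between 10787935 and 10796823, and Tnp1 lies on chromosome 1. Prm3 fell by 3.55 ± 0.11. Among genes outside the lists, Faiml (-4.29 ± 0.26), Tex37 (-3.67 ± 0.26), Ttc24 (-3.67 ± 0.17) and Dydc2 (-3.54 ± 0.23) completed the 10 largest decreases.

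The CREM program list was named after CREM, an activator of genes in round spermatids. It was drawn up with Crem itself and its coactivator Fhl5 in it, so it is not a list of CREM targets alone. In RNA it had 15 of 34 members lower and 5 higher (adjusted p = 0.00549, but adjusted p = 0.309 with an estimated correlation), and the same counts when adjusted over the list alone. Dnajb8 fell by 2.30 ± 0.14, the spermatid linker histone H1fnt by 1.95 ± 0.10 and the testis angiotensin-converting enzyme Ace by 1.41 ± 0.09. Acrosome genes split, 13 lower and 7 higher of 35 (13 and 9 when adjusted over the list alone), and the list did not pass (adjusted p = 0.426). Its median was 0.0111 while its mean was -0.126, and with a trend on coding length removed 10 were lower and 11 higher, with a median of 0.24. Sppl2c fell by 2.11 ± 0.11 and Izumo2 by 1.82 ± 0.14, whereas Spaca5 rose by 1.28 ± 0.17. Of the 20 testis-specific energy metabolism genes, 7 fell and 1 rose, also when adjusted over the list alone, without passing as a list (adjusted p = 0.0628), though it passed without WT RNA replicate 1 (0.0391) and without null RPF replicate 1 (0.043). With the length trend removed 5 were lower and 3 higher, and the median went from -0.23 to -0.00856. The sperm glycolytic enzyme gene Gapdhs fell by 1.85 ± 0.17.

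Of the 28 piRNA pathway genes 14 rose and 3 fell, Piwil1 among the latter, and the counts were the same when adjusted over the list alone. Piwil1 is the gene removed by the genotype, so its fall was fixed in advance and weighs against a rise of the list. No list test without it was run. Tdrd1, a scaffold of the piRNA machinery, rose by 2.08 ± 0.08, the piRNA methyltransferase gene Henmt1 by 1.37 ± 0.13 and Tex15 by 1.22 ± 0.11. The list as a whole did not pass (adjusted p = 0.0628), though it did without TMM (0.0316), without WT RNA replicate 2 (0.0107) and without null RPF replicate 2 (0.0474). Meiotic prophase genes had 14 of 36 higher and 3 lower, the same when adjusted over the list alone (list adjusted p = 0.0557). That list passed without WT RNA replicate 2 (0.0107) and without any single footprint library, at 0.0466 and 0.049 without WT RPF replicates 1 and 2 and 0.0488 and 0.0474 without null RPF replicates 1 and 2. Of the genes of the synaptonemal complex, Sycp2 rose by 1.37 ± 0.11 and Syce3 fell by 1.66 ± 0.12. Genes from pachytene to the meiotic division had 6 of 26 higher and 5 lower by either adjustment (list adjusted p = 0.426), with a median of -0.136 and a mean of 0.0451. Cenpe, a kinetochore motor, rose by 1.27 ± 0.10 and Ttk by 1.21 ± 0.10. Spermatogonial markers had 12 of 24 lower and 1 higher by either adjustment (adjusted p = 0.0473, and adjusted p = 0.21 with an estimated correlation). That call ended without null RNA replicate 1 (0.0521), WT RPF replicate 1 (0.06) or WT RPF replicate 2 (0.0651), and once the length trend was removed (0.0646, with 7 lower and 1 higher). Among the markers Rhox13 fell by 1.18 ± 0.24 and Epcam by 0.95 ± 0.12 on the log2 scale.

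Markers of the somatic cell types moved apart. Of the 20 myoid and smooth muscle genes 14 fell and 0 rose (16 and 1 when adjusted over the list alone), with a median of -0.92 and an adjusted p of 2.71e-08. Collagens Col3a1 and Col1a1 fell by 2.33 ± 0.15 and 2.19 ± 0.11. Of 30 Sertoli genes 18 fell and 0 rose (20 and 0 when adjusted over the list alone, adjusted p = 0.000727, and adjusted p = 0.14 with an estimated correlation). With the length trend removed 13 were lower and 1 higher, and the median went from -0.59 to -0.35. Sox9, the Sertoli cell transcription factor, fell by 1.54 ± 0.15 and Aard by 1.46 ± 0.14. Leydig markers had 7 of 21 higher and 3 lower (9 and 3 when adjusted over the list alone, adjusted p = 0.00549, and adjusted p = 0.309 with an estimated correlation). Star and Hsd17b3, which act in testosterone synthesis, rose by 1.59 ± 0.11 and 1.60 ± 0.21, and Insl3, a Leydig hormone, by 1.39 ± 0.09. Macrophage and immune genes had 5 of 20 higher and 1 lower by either adjustment (list adjusted p = 0.381), with Lyz2 at 0.85 ± 0.12 and Aif1 at -1.02 ± 0.20. Endothelial and blood genes had 8 of 15 lower and 0 higher (8 and 1 when adjusted over the list alone), and did not pass as a list (adjusted p = 0.0763, but 0.0115 without WT RNA replicate 2).

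Cytosolic ribosomal protein genes fell in RNA, 35 of 80 lower and 1 higher (41 and 1 when adjusted over the list alone), with a median of -0.51 and an adjusted p of 6.52e-05. That call did not hold with an estimated correlation (adjusted p = 0.14 with an estimated correlation) or once a trend on coding length was removed (18 lower and 3 higher, median -0.18, adjusted p = 0.0786). Rpl36a fell by 1.71 ± 0.19 on the log2 scale. Mitochondrially encoded transcripts had 9 of 12 lower and 1 higher by either adjustment (adjusted p = 0.00549, and adjusted p = 0.309 with an estimated correlation), with mt-Nd1 at -1.36 ± 0.11. Chaperone genes had 10 of 17 lower and 1 higher (10 and 2 when adjusted over the list alone, adjusted p = 0.0109, and adjusted p = 0.149 with an estimated correlation), led by the spermatid chaperone Hspa1l at -2.34 ± 0.11. The remaining lists did not pass. Translation factors had 18 of 52 lower and 4 higher (21 and 4 when adjusted over the list alone, list adjusted p = 0.15), RNA-binding regulators 14 of 53 lower and 11 higher (14 and 12, list adjusted p = 0.801), stress response genes 6 of 28 lower and 2 higher by either adjustment (0.558), and p53 response genes 4 of 22 higher and 2 lower by either adjustment (0.273). With the length trend removed 9 translation factors were lower and 5 higher, and their median went from -0.17 to -0.0376. The median of the RNA-binding list was 0.0549 and its mean -0.114. The median of the stress response list, -0.0581, became 0.0397 without TMM, 0.00619 with TMM within each assay and 0.0977 once the length trend was removed, and that of the pachytene list became 0.0931 with the last.

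The 10 largest RNA increases were led by AY358078 (4.03 ± 0.21) and included Bhmt (3.67 ± 0.11), a methyltransferase of homocysteine metabolism, Ptgds (3.50 ± 0.11), which makes prostaglandin D, and Tapbpl (3.36 ± 0.16). Stambp (3.31 ± 0.28), Muc16 (3.25 ± 0.15), Zfp184 (3.21 ± 0.10), the apolipoprotein gene Apoc1 (3.10 ± 0.18) and the myosin gene Myo1e (3.04 ± 0.16) followed. Without TMM the share of higher genes among RNA calls was 55.1%, against 44.1% with it, and with the 4 RNA libraries fitted alone 9044 genes were called. Leaving out an RNA library gave 3279 calls without WT RNA replicate 1, 3925 without WT RNA replicate 2, 3247 without null RNA replicate 1 and 3321 without null RNA replicate 2.

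The footprint comparison asked which mRNAs were occupied by more or fewer ribosomes in the null testes. Several genes of late spermatids lost nearly all of their footprints, among them Cabs1, Tnp2, Prm2, Prm1 and Tnp1. Cabs1, a calcium-binding protein of spermatids, went from 411 ± 53.2 CPM (SD, n = 2) in WT RPF to 2.42 ± 0.0107 in null, a fall by 7.40 ± 0.15 on the log2 scale. Tnp2 footprints fell by 7.08 ± 0.13, Prm2 by 6.92 ± 0.22, Prm1 by 6.50 ± 0.13 and Tnp1 by 6.09 ± 0.15. Among 21 Leydig genes 8 gained footprints and 1 lost them (list adjusted p = 0.157 with an estimated correlation), and Sult1e1 rose by 3.65 ± 0.12 and Insl3 by 2.28 ± 0.09. In all, 4075 of 16051 genes were called, 1933 higher and 2142 lower, with 586 and 1025 changed more than 2-fold.

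Of the 33 late spermiogenesis genes 28 lost footprints and 2 gained them (29 and 2 when adjusted over the list alone), with a median of -3.58 (adjusted p = 4e-107). Camera with an estimated correlation gave an adjusted p of 0.0062. Odf1, of the outer dense fibres of the tail, fell by 6.01 ± 0.16 from 445 ± 56.9 CPM to 7.02 ± 1.2. Akap4, the main protein of the fibrous sheath of the tail, fell by 5.23 ± 0.13 from 121 ± 12 CPM to 3.17 ± 0.318. Both that gained footprints were tektins of the axoneme, Tekt4 by 0.49 ± 0.09 and Tekt2 by 0.33 ± 0.08, and they were named after their values were seen. With the 4 footprint libraries alone neither Tekt4 in RPF nor Tekt2 in RPF passed (adjusted p = 0.0765 and 0.185), and Tekt2 in RPF did not without null RNA replicate 1 (0.0591), null RNA replicate 2 (0.0591) or null RPF replicate 1 (0.0593). Other genes with near loss were Tppp2 (-6.22 ± 0.15), the protease gene Prss58 (-6.14 ± 0.28) and Cstl1 (-6.14 ± 0.31). Tex37 had a mean of 34.3 ± 2.85 CPM (SD, n = 2) in WT RPF and 0.33 ± 0.466 in null RPF, where 1 library had 0 counts.

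The CREM program had 14 of 34 members lower and 3 higher (17 and 4 when adjusted over the list alone, adjusted p = 3.5e-10, and adjusted p = 0.0776 with an estimated correlation). Dnajb8 fell by 5.98 ± 0.21, Fhl5, a coactivator of CREM, by 4.37 ± 0.16, the mitochondrial protein gene Spata19 by 3.35 ± 0.12 and Pgk2, the glycolytic kinase of sperm, by 3.05 ± 0.12. Acrosome genes had 18 of 35 lower and 2 higher (22 and 2 when adjusted over the list alone) with a median of -0.61 (adjusted p = 2.6e-05, and adjusted p = 0.0584 with an estimated correlation). Among them Sppl2c fell by 3.88 ± 0.12, Izumo2 by 1.79 ± 0.13 and Spaca7 by 1.38 ± 0.11. Spermatogonial markers had 6 of 24 lower and 0 higher (6 and 1 when adjusted over the list alone, list adjusted p = 0.139). The largest fall was that of Tex13a at -4.37 ± 0.28. Its RNA fell by 0.48 ± 0.15 and its TE by 3.89 ± 0.34, while the median TE change of the list was 0.317. Tex13a thus does not stand for the list. Energy metabolism genes had 5 of 20 lower and 2 higher by either adjustment (0.251), with Gapdhs at -2.32 ± 0.18.

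Leydig genes had 8 of 21 higher and 1 lower in footprints (9 and 2 when adjusted over the list alone, adjusted p = 7.32e-07, and adjusted p = 0.157 with an estimated correlation), with Star at 2.17 ± 0.10 and Hsd17b3 at 1.45 ± 0.19. Myoid genes had 10 of 20 lower and 0 higher (10 and 1 when adjusted over the list alone, adjusted p = 4.67e-05, and adjusted p = 0.0584 with an estimated correlation), with Col3a1 at -2.48 ± 0.15 and Col1a1 at -2.21 ± 0.11. Mitochondrially encoded genes had 6 of 12 lower and 0 higher by either adjustment (adjusted p = 0.0191, and adjusted p = 0.349 with an estimated correlation), with mt-Nd5 at -1.12 ± 0.17. The footprints of ribosomal protein genes did not pass as a list, 3 of 80 higher and 3 lower (2 and 2 when adjusted over the list alone, list adjusted p = 0.922). Their median was -0.0469 while the test pointed up, and the median became 0.0195 once the length trend was removed.

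In the piRNA pathway 10 of 28 genes gained footprints and 3 lost them (10 and 4 when adjusted over the list alone, list adjusted p = 0.299), with a median of 0.15 and a mean of -0.00983. Piwil1, removed by the genotype, is among the 3 that lost them (log2 change -7.05), which lowers the mean and weighs against a rise of the list. Tdrd1 rose by 1.77 ± 0.08, Henmt1 by 1.04 ± 0.13 and Piwil2, the PIWI protein of earlier germ cells, by 0.68 ± 0.09. The other lists did not pass either. They were Sertoli (8 of 30 lower, 2 higher by either adjustment, list adjusted p = 0.445), endothelial and blood (8 of 15 lower, 1 higher by either adjustment, 0.125, but 0.0257 and 0.0231 without WT RNA replicates 1 and 2) and macrophage and immune (6 of 20 higher, 2 lower by either adjustment, 0.454). Meiotic prophase had 5 of 36 lower and 2 higher (5 and 1 when adjusted over the list alone, 0.922) and pachytene to meiotic division 5 of 26 higher and 0 lower by either adjustment (0.139). Translation factors had 5 of 52 lower and 2 higher by either adjustment (0.922), RNA-binding regulators 5 of 53 higher and 4 lower (4 and 4 when adjusted over the list alone, 0.947), and chaperones 4 of 17 lower and 2 higher (4 and 3 when adjusted over the list alone, 0.139). Stress response genes had 4 of 28 lower and 2 higher (3 and 2 when adjusted over the list alone, 0.979), and p53 response genes 3 of 22 higher and 0 lower by either adjustment (0.195). Median and mean differed in sign for chaperones (0.00319 and -0.378) and translation factors (0.0249 and -0.0117). For the stress response list both lay above 0 (0.115 and 0.0493) while the test pointed down. Without TMM the medians of the chaperone, macrophage and translation factor lists turned to -0.0413, -0.0292 and -0.0216, and with DESeq2 size factors those of the RNA-binding and energy metabolism lists turned to 0.00378 and 0.0131. Removing the length trend turned the chaperone median to -0.0345 and the energy metabolism median to 0.0101.

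The genes that gained most footprints were AY358078 (4.47 ± 0.18), Bhmt (4.27 ± 0.11), Apoc1, Ptgds (3.75 ± 0.11) and Sult1e1. Agt, the precursor of angiotensin, followed at 3.09 ± 0.13, then Wdfy1 (2.95 ± 0.21), Lrg1 (2.87 ± 0.13), Stambp (2.70 ± 0.27) and Morc1 (2.49 ± 0.20), which silences transposons in the male germ line. Footprint replicates spread more than RNA replicates and shared one error estimate with them, so the footprint calls lean on the tighter RNA libraries. With the 4 footprint libraries fitted alone 1984 genes were called, 48.4% of the 4075 being kept, and with WT RPF replicate 1 blocked with null RPF replicate 2 and the other two together, a pairing chosen after seeing that same-numbered footprint libraries deviated in opposite ways (r = -0.83 across 9731 genes), 8179 were called.

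RNA and footprint changes ran together across genes, with a Pearson r of 0.585 over 16051 genes, which are not independent replicates. Of these genes 1001 were called higher in both assays, against 317.8 for independent lists of those sizes, and 1267 lower in both, against 446.9. Opposite calls were fewer than for independent lists: 112 genes were lower in RNA and higher in footprints, against 403.3, and 108 were higher in RNA and lower in footprints, against 352.2.

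**Figure D1:**
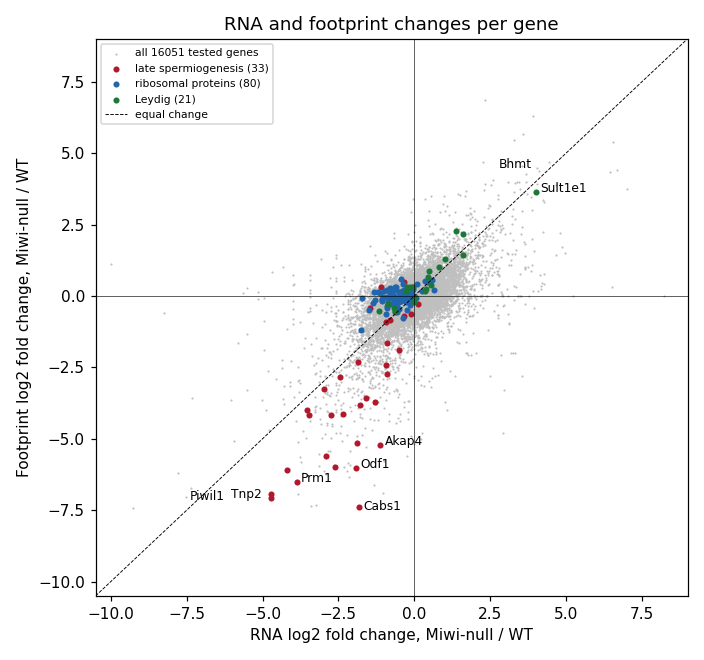
Log2 fold change in RNA (x axis) against log2 fold change in footprints (y axis), Miwi-null over WT, for 16051 tested genes (grey), with the late spermiogenesis (33 genes, red), ribosomal protein (80, blue) and Leydig (21, green) lists coloured and a dashed line of equal change. Late spermiogenesis genes lie below the dashed line in the main, as with Cabs1 at -1.82 in RNA and -7.40 in footprints, and 35 of the 80 ribosomal protein genes were lower in RNA against 3 in footprints (RNA list adjusted p = 0.14 with an estimated correlation).

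The TE comparison asked where footprints changed by more or less than the RNA did. Several spermatid genes, among them Cabs1, Akap4 and Odf1, lost footprints far beyond the loss of their RNA. Cabs1 TE fell by 5.59 ± 0.18 on the log2 scale, Akap4 by 4.10 ± 0.16 and Odf1 by 4.10 ± 0.19 (edgeR adjusted p = 8.05e-06, 1.63e-05 and 3.72e-05). On GRCm38 they lie on chromosome 5 (87979451 to 87981541), X (7067515 to 7078609) and 15 (38219203 to 38226735). Akap4 RNA stood at 1264 ± 24.0 CPM (SD, n = 2) in WT and 578 ± 0.973 in null, while its footprints nearly disappeared. Of 80 ribosomal protein genes 18 rose in TE and 0 fell (list adjusted p = 0.0848 with an estimated correlation). The test called 2399 of 16051 genes, 1184 higher and 1215 lower, with 411 and 564 changed more than 2-fold. Of the 1184, 705 had lower RNA and no called footprint change. Of the 1215, 523 had higher RNA and no called footprint change. A TE call therefore need not come with a called change in footprints.

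Of the 33 late spermiogenesis genes 19 fell in TE and 4 rose (24 and 4 when adjusted over the list alone), with a median of -1.41 (adjusted p = 1.02e-36, and adjusted p = 0.00962 with an estimated correlation). Smcp, of the mitochondrial capsule, fell by 3.37 ± 0.54 and Oaz3, the testis antizyme, by 3.28 ± 0.23. The protamine and transition protein genes fell in TE as well as in RNA, Prm1 by 2.62 ± 0.15, Tnp2 by 2.35 ± 0.15, Prm2 by 2.21 ± 0.25 and Tnp1 by 1.89 ± 0.17. Spem1 in TE (-0.28 ± 0.35) did not pass, although its RNA fell, and neither did Prm3 in TE (-0.45 ± 0.15), which passed without TMM (adjusted p = 0.0349), with TMM within each assay (0.0471) and with the length trend removed (0.0104).

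The 4 late spermiogenesis members that rose in TE, named after their values were seen, each lost the call without some single library. Fabp9 in TE (1.41 ± 0.37) lost it without WT RNA replicates 1 and 2 (adjusted p = 0.111 and 0.13), null RNA replicates 1 and 2 (0.129 and 0.132) and null RPF replicate 1 (0.0716). Meig1 in TE (1.04 ± 0.19) lost it without WT RNA replicate 2 (0.0546) and null RNA replicates 1 and 2 (0.0721 and 0.0584). With the length trend removed Fabp9 in TE, Meig1 in TE and Tekt2 in TE did not pass (0.0949, 0.0849 and 0.0789). Tekt4 in TE (0.84 ± 0.13) lost it without null RNA replicate 1 (0.0549). Tekt2 in TE (0.41 ± 0.11) lost it without WT RNA replicates 1 and 2 (0.154 and 0.103), null RNA replicates 1 and 2 (0.195 and 0.191), WT RPF replicate 1 (0.0596) and null RPF replicates 1 and 2 (0.083 and 0.102), and without TMM (0.144).

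**Figure D2:**
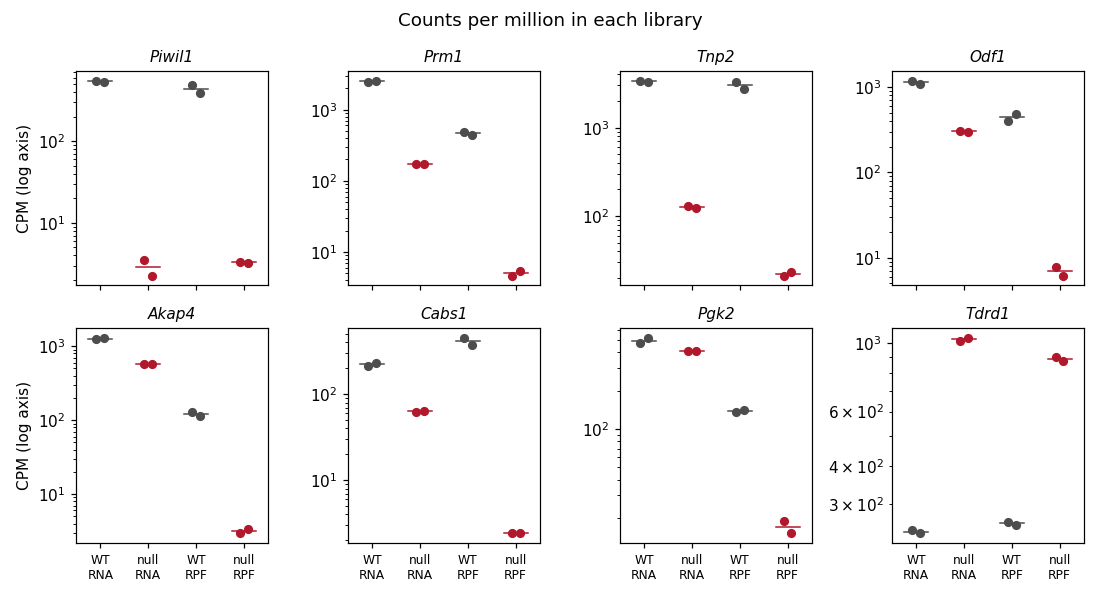
TMM-scaled CPM (log axis) of 8 genes in each of the 8 libraries, WT in grey and Miwi-null in red, with a point for each library and a line at the mean of 2. Akap4 falls from 1264 to 578 in RNA but from 121 to 3.17 in footprints, and Pgk2 stands at 497 and 411 in RNA against 139 and 17.0 in footprints.

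Outside that list, Pgk2 TE fell by 2.78 ± 0.16, with RNA at 497 ± 29.9 CPM in WT and 411 ± 1.35 in null. Galntl5 RNA did not pass at -0.19 ± 0.15, and its TE fell by 3.86 ± 0.24. Prss58 (-3.91 ± 0.36), Tex13a (-3.89 ± 0.34), Fabp12 (-3.81 ± 0.22), Lelp1 (-3.79 ± 0.42) and the histone variant gene H2al3 (-3.69 ± 0.47) were further among the 10 largest. Ppef1 RNA rose by 1.19 ± 0.18 while its footprints fell by 2.62 ± 0.24, a TE change of -3.80 ± 0.30. In the CREM program 10 of 34 genes fell and 4 rose (14 and 7 when adjusted over the list alone, adjusted p = 2.12e-05, and adjusted p = 0.191 with an estimated correlation), with Dnajb8 at -3.68 ± 0.26, Fhl5 at -3.53 ± 0.21 and Spata19 at -2.35 ± 0.16. In the acrosome list 9 of 35 fell and 0 rose (18 and 1 when adjusted over the list alone), with a median of -0.56 (adjusted p = 0.000107, and adjusted p = 0.0793 with an estimated correlation), and 15 fell with the length trend removed. Sppl2c fell by 1.77 ± 0.15 and the sperm surface protein gene Adam3 by 1.60 ± 0.12, the latter against an RNA rise by 0.73 ± 0.08.

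Ribosomal protein genes had 18 of 80 higher in TE and 0 lower (20 and 0 when adjusted over the list alone), with a median of 0.39 (adjusted p = 8.07e-07, and adjusted p = 0.0848 with an estimated correlation). Rpl36a rose by 1.65 ± 0.25 and Rpl19 by 1.45 ± 0.17, each with lower RNA. Once the length trend was removed the list median was 0.14, with 10 higher and 0 lower (adjusted p = 0.00336, and adjusted p = 0.0697 with an estimated correlation). The single genes that rose most in TE also had lower RNA in most cases, the exception among the 10 being Wdfy1 (TE 2.09 ± 0.27). Lower RNA raises TE by definition, so that pairing is no separate result. Footprints of Atp5k, Ndufa13, Edf1, Sdc3, Hist1h2bl and Ubald2 did not pass, while those of Hist2h2ab, Hypk, Osgin1 and Wdfy1 rose. Hypk, a partner of the N-terminal acetyltransferase, rose by 2.99 ± 0.29 with an RNA fall by 2.32 ± 0.22, Ndufa13 of respiratory complex I by 2.14 ± 0.18 and Osgin1 by 2.85 ± 0.17. Atp5k (3.04 ± 0.50), Edf1 (1.95 ± 0.27), Sdc3 (1.94 ± 0.31) and the histone gene Hist2h2ab (3.23 ± 0.48) rose too. Hist1h2bl (2.05 ± 0.37) lost its call without WT RNA replicate 1 (adjusted p = 0.0606) and without null RNA replicate 1 (0.063). Ubald2 in TE (2.04 ± 0.41) lost it without any single RNA library, at adjusted p-values of 0.0687 and 0.0646 without WT RNA replicates 1 and 2 and 0.0703 and 0.0623 without null RNA replicates 1 and 2, and at 0.0907 without null RPF replicate 2.

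Sertoli genes had 9 of 30 higher in TE and 0 lower (10 and 2 when adjusted over the list alone, adjusted p = 0.00225, and adjusted p = 0.172 with an estimated correlation), with Sox9 at 1.84 ± 0.21 and Aard at 1.52 ± 0.20. With the length trend removed 7 were higher and 2 lower, and the median went from 0.29 to 0.12. These Sertoli genes fell in RNA (median -0.59), Sox9 and Aard among them, and their footprints did not pass as a list (median -0.21). The TE rise thus goes with the fall in RNA and not with a gain of footprints. Meiotic prophase genes had 8 of 36 lower and 1 higher (11 and 1 when adjusted over the list alone, adjusted p = 0.0288, adjusted p = 0.563 with an estimated correlation, and 0.0934 without WT RNA replicate 1). Syce3 rose by 1.16 ± 0.17. The piRNA pathway had 3 of 28 lower and 1 higher (2 and 1 when adjusted over the list alone, list adjusted p = 0.601), and Tdrd1 in TE did not pass at -0.31 ± 0.11 (adjusted p = 0.098, but 0.0326 without TMM). The other lists did not pass in TE. They were myoid (3 of 20 higher, 0 lower, and 4 and 1 when adjusted over the list alone, list adjusted p = 0.0563, but 0.0469 without null RPF replicate 2 and 0.0423 with the length trend removed, and adjusted p = 0.222 and, with that trend removed, 0.188 with an estimated correlation), Leydig (2 of 21 higher, 0 lower by either adjustment, 0.132, but 0.0228 without WT RPF replicate 1) and macrophage and immune (2 of 20 lower, 1 higher, and 2 and 2 when adjusted over the list alone, 0.813). Endothelial and blood had 3 of 15 higher and 1 lower by either adjustment (0.978), spermatogonia 2 of 24 lower and 1 higher (2 and 3 when adjusted over the list alone, 0.626) and pachytene to meiotic division 4 of 26 higher and 3 lower (6 and 4 when adjusted over the list alone, 0.601). Translation factors had 9 of 52 higher and 3 lower (11 and 3 when adjusted over the list alone, 0.0563, but 0.0308 without WT RNA replicate 1, 0.0103 without WT RPF replicate 2 and 0.0167 without null RPF replicate 2), RNA-binding regulators 8 of 53 higher and 4 lower by either adjustment (0.937) and mitochondrially encoded genes 1 of 12 lower and 0 higher by either adjustment (0.878). Energy metabolism had 3 of 20 higher and 1 lower (5 and 2 when adjusted over the list alone, 0.769) and chaperones 5 of 17 higher and 3 lower (7 and 4 when adjusted over the list alone, 0.601). Stress response genes had 4 of 28 higher and 3 lower (6 and 3 when adjusted over the list alone, 0.769), and p53 response genes 1 of 22 lower and 0 higher (0 and 0 when adjusted over the list alone, 0.937). Median and mean differed in sign for endothelial and blood (0.101 and -0.129) and mitochondrially encoded genes (-0.0645 and 0.0158). The mitochondrial median was -0.213 without TMM and -0.308 with the length trend removed. Without TMM the medians of the endothelial, stress, p53, pachytene and RNA-binding lists turned to -0.039, -0.0921, -0.0094, -0.0273 and -0.139. The RNA-binding median was also below 0 with DESeq2 size factors (-0.0138), with TMM within each assay (-0.0588, the stress list being at -0.0108) and with the length trend removed. That removal turned the endothelial, stress, p53 and energy metabolism medians to -0.0715, -0.0376, -0.00912 and -0.00798.

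**Figure D3:**
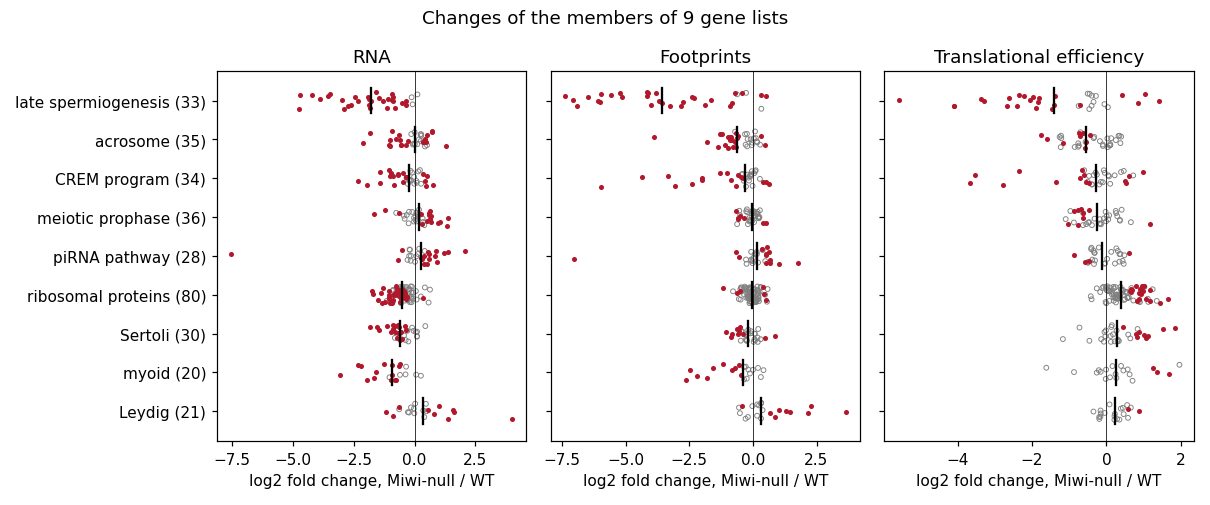
Log2 fold changes, Miwi-null over WT, of each member of 9 gene lists in RNA, footprints and translational efficiency, with list sizes in brackets, filled red points for called genes, open points for the others and a black bar at the list median. The late spermiogenesis median lies at -1.78 in RNA, -3.58 in footprints and -1.41 in TE, and the ribosomal protein median at -0.51, -0.05 (0.0195 once the length trend is removed) and 0.39.

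Without TMM the median TE change of all genes shifted by -0.143 and 29.1% of TE calls were higher, against 49.4% with it and 37.7% with the length trend removed. TE calls numbered 643 without WT RNA replicate 1, 976 without WT RNA replicate 2, 622 without null RNA replicate 1, 654 without null RNA replicate 2 and 3637 without WT RPF replicate 2, and 1236 with the replicate number as a block, against 6549 with the crossed pairing of footprint libraries.

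The authors' deposited table gives the same direction for TE wherever both made a call. Of its 3952 genes marked Down, 1120 were called lower in TE here and 0 higher, and of its 3681 marked Up, 1101 were called higher and 0 lower. Its merged log2 change was -5.73 for Cabs1, -4.20 for Akap4, -4.21 for Odf1 and 2.91 for Hypk. Across 12500 genes the authors' deposited table and the TE changes computed here had a Pearson r of 0.978, both resting on the same counts. Between the authors' deposited tables of single replicates, 1605 genes were marked Up in both, 2175 Down in both and 1225 in opposite directions.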

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

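The removal of the coding-length trend, the canonical transcript and the crossed pairing were chosen after the results were seen. The other alternatives were planned. Leaving out each library in turn gave 3247 to 7093 calls in RNA, 2944 to 5163 in RPF and 622 to 3637 in TE, against 5988, 4075 and 2399. It gave 8 to 12, 6 to 7 and 6 to 8 passing lists, against 9, 6 and 6. The lone library of a group was then assumed to vary like the other groups. Each assay's own 4 libraries gave 9044 calls in RNA and 1984 in RPF. Against 1.5-fold, glmTreat called 1930, 1341 and 449. The replicate number as a block gave 5019, 3060 and 1236 calls, and a block of matched RNA and RPF within genotype 1838 in TE. Deviations of same-numbered libraries correlated across 9731 genes at 0.0174 between the RNA groups, -0.83 between the RPF groups, 0.082 within WT and 0.0182 within null. The footprint value may come from a batch that joins WT RPF replicate 1 with null RPF replicate 2 and the remaining pair; the labels name no batch, so this stays open. That crossed pairing, taken from the footprint values themselves, gave 8179 calls in RPF and 6549 in TE. With an estimated correlation 2, 1 and 1 lists passed, late spermiogenesis in each contrast and myoid in RNA, and fry, which does not compare a list with other genes, passed 16, 13 and 6. The RNA call of the spermatogonia list ended once the length trend was removed (adjusted p = 0.0646), and the TE call of meiotic prophase under fry (0.0561). The correlation of RNA and RPF changes, 0.585, was 0.623 at a mean CPM of at least 10 in both assays, 0.499 and 0.529 within replicates 1 and 2 alone, and 0.478 by Spearman. Of 433 called results of named genes and list members, 264 kept direction and call under every alternative run, 0 reversed, 166 lost the call against 1.5-fold and 120 without some single library. Of 143 that were not called, 78 were called under some alternative. The genes followed were the named genes, the members of each list with the largest called changes, and all late spermiogenesis members. Apart from the last, they were picked for large changes in these same data, so these counts do not describe the calls at large. The pseudocount alternative had no use because the values are counts, and the merged table gave no separate value. The causes of these differences were not tested. Leaving out a library lowered the calls in some fits and raised them in others, so the number of libraries alone does not explain them. Depth limits genes of few counts, since 3 counts correspond to 0.106 to 0.269 CPM.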

Other observations

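All tests that weigh an explanation below were chosen after the results were seen. The X chromosome held a larger share of genes with fewer footprints than any single autosome: 131 of its 716 tested genes were lower (18.3%), with a median log2 change of -0.18, against 10.7% to 16.1% on the autosomes. The difference was not tested. Within 10 Mb of Piwil1, 28 of 238 genes were called in RNA and changed more than 2-fold (11.8%), against 13.2% elsewhere. Among translation factors, Eif4g1 footprints fell by 0.97 ± 0.10 on the log2 scale, and among RNA-binding regulators Mex3d fell by 2.15 ± 0.10 in RNA and by 2.46 ± 0.10 in footprints. Zmat3, a p53 target, rose by 1.12 ± 0.12 in RNA and by 0.93 ± 0.12 in footprints.

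Of 33 late spermiogenesis genes 19 were lower in TE and 4 higher, with a median of -1.41 (adjusted p = 0.00962 with an estimated correlation). A trend on coding length is argued against as the whole cause, as the median was -1.48 once it was removed (adjusted p = 0.0115 with an estimated correlation). A shortage of the later cells that translate stored mRNAs may give the same pattern and stays open, because whole testes hold no value per stage; 19 of the 32 members with a mean CPM of at least 10 were lower. A direct effect of MIWI on translation is a biological alternative, and these data do not separate it from that shortage.

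Of 80 cytosolic ribosomal protein genes 35 were lower in RNA and 18 higher in TE (list adjusted p = 0.14 and 0.0848 with an estimated correlation). Short coding sequences in general moved this way, with median RNA changes of -0.50 up to 300 nt and 0.096 in the longest class. Among 10000 random lists matched on coding length, the list's RNA median stood at percentile 0.51 and its TE median at 99.1, but removing the trend moved the RNA median from -0.51 to -0.18 and ended that call (adjusted p = 0.0786), so by a rule set after both values were seen the trend cannot be told apart from a change of this list in RNA. For TE the median went from 0.39 to 0.14, which still passed with the preset correlation (adjusted p = 0.00336) but not with an estimated one (0.0697). Footprints did not pass as a list (median -0.0469, and 0.0195 once the trend was removed), so the TE rise mirrors the RNA fall. The random lists were drawn gene by gene, so their spread leaves out any correlation between members. The trend thus stays open for TE as well. Longer inserts of the null RNA libraries could add to the trend: the WT pair predicts -0.13 for the shortest genes against -0.50 observed, which rests on 1 pair of libraries and stays open.

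Somatic marker lists differed in RNA: 14 of 20 myoid genes and 18 of 30 Sertoli genes were lower, and 7 of 21 Leydig genes were higher and 3 lower. With an estimated correlation the adjusted p was 0.029 for myoid, 0.14 for Sertoli and 0.309 for Leydig. A lower share of germ cells alone would raise them together. The upper quartile of the myoid list was -0.61 while the Leydig median was 0.36, which argues against it as the whole cause. That rule was set after both values were seen, and a lower share could still act beside other changes. Dissection or interstitial content that differs between animals might move these lists apart and stays open, since the Leydig median differed by 0.10 between replicate numbers and 2 libraries per group exclude nothing. A genotype effect on these cells was not tested apart from it.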
